A study of Mus musculus with 18 samples.

How the data were processed

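RNA was measured in mouse cells on 1-colour Affymetrix whole-transcript arrays. Per the labels' protocols, the cells were sorted, cultured for 24 h with or without treatment, lysed in TRIzol, and the purified total RNA was labelled with biotin by a GeneChip whole-transcript kit. There were 18 arrays in 6 groups of 3: AML and LSK cells, each as control, with Dox, and with the compound mix. The groups were taken from the sample titles.

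The deposited values are log2 expression values of probe sets made by the authors with RMA (background correction, normalization between arrays and probe summary), per the submitters' processing notes. The RMA version, the genome build and any further centring are not given in the sources used here. The values were used as deposited, with no further scaling. Scanner files were not used here.

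The table held 41345 probe sets. The probe table named 1 gene for 23521 of them and several genes for 1814, and did not list 16010. Of the probe sets with 1 gene, 23328 had an Entrez ID that matched the mouse RefSeq gene table, and 0 symbols needed an update. Only probe sets with 1 gene were named. For each of the 22180 different genes the probe set with the highest mean over all 18 arrays was kept, and different probe sets of a gene were not compared. Genes were then tested if they lay above the 40th percentile of all probe sets of the same array on at least 3 arrays, which left 16583.

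Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 18 arrays, contrasts and eBayes), with Benjamini-Hochberg adjustment over all genes tested in a comparison and an adjusted p threshold of 0.05. The fit had 12 residual degrees of freedom and a prior of 2.79 degrees of freedom (prior SD 0.273 log2). Without LSK compound replicate 1 the prior had 5.31 degrees of freedom and an SD of 0.143. There were 9 comparisons: each treatment against its control in each cell type, the difference between the cell types in each response, AML against LSK control, and Dox against compound in each cell type. The arrays carry no read depth, so their number limits the precision.

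A total of 36 gene lists with 646 entries were tested: reprogramming factors, pluripotency network, epithelial, mesenchymal, p53 targets, pro-apoptotic, anti-apoptotic, CDK inhibitors, mitosis, DNA replication, DNA damage and repair, MLL-AF9 program, stem and progenitor, granule and neutrophil, monocyte and macrophage, dendritic and antigen presentation, erythroid, megakaryocyte and platelet, mast cell and basophil, B cell, T and NK cell, stromal and endothelial, ribosome biogenesis and Myc targets, unfolded protein and integrated stress response, oxidative stress response, interferon response, NF-kB and inflammatory, Wnt and beta-catenin targets, TGF-beta targets, LSD1 and Gfi1 repressed, lysosome and autophagy, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded, chromatin regulators, and heat shock genes. Of the entries 576 had a probe set of that gene alone. The probe table names the mitochondrially encoded genes by their older symbols, and these were matched to the list after the data were seen. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over all lists in a comparison, and with fry. List members were also adjusted over the list alone.

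The genes named follow a fixed rule. Pou5f1, Sox2, Klf4 and Myc are always given. For each treatment against its control and for AML against LSK control, the rule takes the 10 largest rises and 10 largest falls among genes past the threshold whose 3 arrays of one group all lie beyond the 3 of the other. For the other comparisons it takes the 5 largest each way past the threshold. From each list reported, it takes up to 4 members with the smallest p. Predicted genes, microRNA and small nucleolar RNA genes and receptor gene segments were left out of the rankings but not of the tests. Genes named outside the rule are said to have been chosen after their values were seen.

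Correlations of log2 changes were computed across genes. For treatments that share control arrays, unchanged groups were simulated against the same controls to give the value with no effect, and the covariance is given beside the correlation. The limma and camera steps were tested on simulated data with 200 of 16583 genes changed by known amounts. With all 18 arrays, 37.3% of genes set to a log2 change of 1 were called for LSK compound against control (1 false call) and 35.8% for AML compound against control (0 false calls). For AML Dox against control, 97.0% of such genes were called when LSK compound replicate 1 was left out, with 6 false calls.

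The alternatives tried were the replicate number as a block, each array left out in turn, a fit on the groups compared alone, centring of each array on its median, quantile normalization, no filter and a stricter filter (60th percentile), all probe sets of the file, an intensity trend with a robust prior, array quality weights, a fold change of at least 2 as well, an estimated correlation per list, and split controls for the correlations. Values under the filter level of an array set to that level, and the granule list without members under it in AML control, were added after the data were seen. Leaving out LSK compound replicate 1 in the comparisons that do not use its group, in the counts of shared genes and of probe sets not paired with 1 gene, and in the ratio of the Dox counts was added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.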

Results

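Mouse leukemia cells and normal blood progenitors were profiled on expression arrays, per the protocols after 24 h in culture. The aim was to ask how each cell type responds to reprogramming factors and to a cocktail of reprogramming compounds, and how the leukemia cells are eliminated. The leukemia cells were GFP-positive acute myeloid leukemia (AML) cells carrying MLL-AF9, a fusion oncogene that transforms blood progenitors. The normal cells were lineage-negative, Kit-positive and Sca1-positive (LSK) cells, a marrow fraction rich in hematopoietic stem and progenitor cells. Per the labels, both came from mice with doxycycline (Dox) inducible transgenes for Oct4 (gene symbol Pou5f1), Sox2, Klf4 and c-Myc. Each cell type was left as a control, given Dox, or given a mix of VPA (a histone deacetylase inhibitor), CHIR (a GSK3 inhibitor), 616452 (a TGF-beta receptor inhibitor) and TCP (an LSD1 inhibitor), called the compound group here. This makes 6 groups of 3 arrays. The labels call the 3 arrays of a group biological repeats, but nothing says that they came from separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical. Values are log2 expression after RMA, and 16583 genes were tested with limma on all 18 arrays.

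Of the 18 arrays, 17 correlated across all probe sets at r between 0.979 and 0.989 within a group and between 0.904 and 0.979 across groups. LSK compound replicate 1 correlated with every other array at only 0.638 to 0.672. Its median was 3.24 (2.65 to 2.75 on the other 17 arrays) and its SD 1.45 (2.01 to 2.08). Transcripts that are abundant in most cells were dim on it: Actb, a cytoskeletal actin, read 4.56 against 8.83 to 9.28 on the other 17 arrays, the glycolytic enzyme Gapdh 5.49 against 11.39 to 11.93, the translation factor Eef2 5.62 against 10.69 to 11.36, and the MHC light chain B2m 4.16 against 12.02 to 12.47. These 4 genes were chosen after their values were seen. The array widened the spread shared by all comparisons, so the count of genes called in each comparison is given without it too, an alternative added after the data were seen. The median standard error of a treatment effect was 0.24 log2 with all 18 arrays, and without that array 0.12, or 0.14 for LSK compound. The number of arrays also limits the precision. For most of the large changes from or to a mean under the filter level (the 40th percentile of each array), the size with such values set to that level is given too, as a lower bound added after the data were seen.

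**Figure D1:**
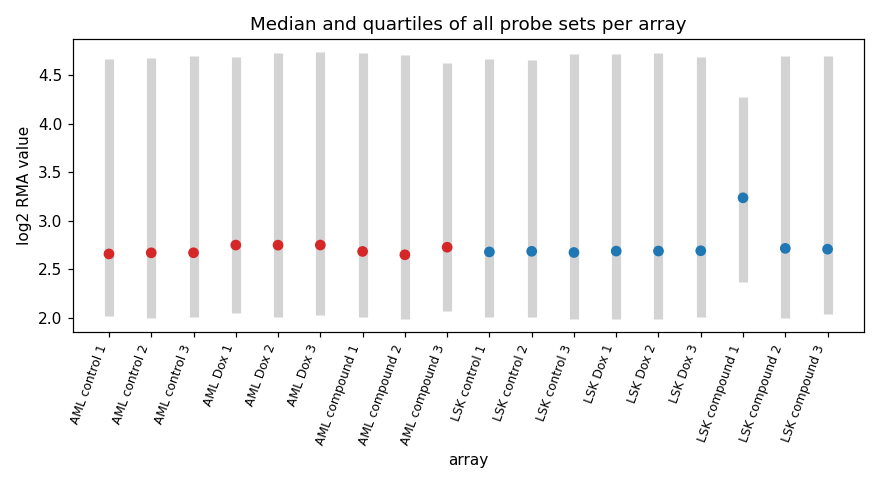
Median (point) and quartiles (gray bar) of the log2 RMA values of all probe sets on each of the 18 arrays, AML in red and LSK in blue. LSK compound replicate 1 has a median of 3.24, and the other 17 arrays lie between 2.65 and 2.75.

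The LSK compound arrays also differed in sex-linked transcripts, which were looked at after Xist appeared among the baseline differences. Xist, the RNA that silences an X chromosome in female cells, read 9.28 to 9.77 on the LSK control and Dox arrays and 2.34 to 3.01 on the 9 AML arrays. On LSK compound replicates 2 and 3 it read 7.35 and 7.32. The Y-linked genes Eif2s3y (5.47 and 5.20), Kdm5d (4.30 and 4.54) and Uty (5.03 and 5.13) were above background on those 2 arrays and at most 2.67 on all others.

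Dox in AML cells lowered genes of DNA replication, ribosome biogenesis and mitosis and raised Akr1c18 from near background. The aldo-keto reductase Akr1c18 rose from 2.51 ± 0.03 to 11.26 ± 0.12 (SD, n = 3), a log2 change of 8.75 (SE 0.20, limma adjusted p = 3.65e-13), and Lix1, under the filter level in the controls, by at least 6.85 (7.29 as measured, SE 0.16, limma adjusted p = 3.65e-13). The actin-binding protein gene Avil (6.25), the immune checkpoint ligand Cd200 (6.07, at least 5.70), the matrix gene Matn2 (5.99) and the BMP receptor Bmpr2 (5.90) were among the largest rises. Ctsg, which encodes the neutrophil granule protease cathepsin G, fell from 10.60 ± 0.03 to 4.49 ± 0.20 (log2 change -6.10, SE 0.15, limma adjusted p = 6.71e-13). The myeloid receptor Clec12a (-5.25), the progenitor surface marker Cd34 (-5.23), the spermidine synthase Srm (-4.50) and the replication licensing factor Cdc6 (-4.32) also fell. In each of these genes all 3 arrays of one group lay beyond all 3 of the other.

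Of the 4 factors, Klf4 rose from 3.27 ± 0.14 to 9.14 ± 0.08 in AML cells under Dox (58.7-fold, SE 0.21 log2, limma adjusted p = 2.36e-11, n = 3). Sox2 rose by 1.31 (SE 0.25, adjusted p = 0.001) to a mean of 4.03, Pou5f1 by 0.67 (SE 0.21, adjusted p = 0.0263) to 3.58, and Myc fell from 8.67 ± 0.04 to 4.57 ± 0.36 (log2 change -4.10, SE 0.64, adjusted p = 0.000151). Which parts of each transcript the probe sets cover, and so whether they read the transgenes, is not given in the sources used here.

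**Figure D2:**
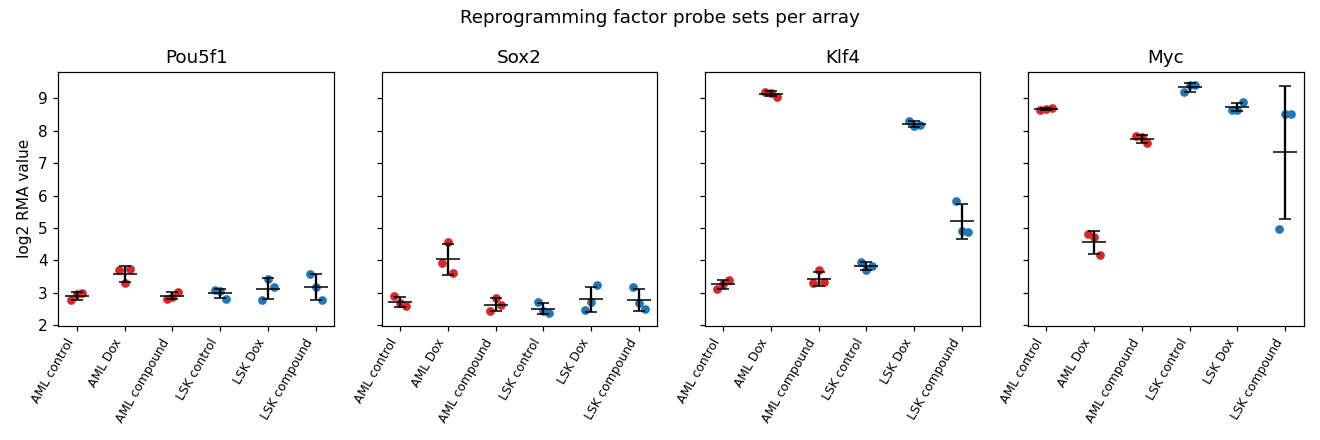
Log2 RMA values of Pou5f1, Sox2, Klf4 and Myc on each array (points, AML in red and LSK in blue) with the group mean and SD of 3 arrays (bars). Klf4 lies at 9.14 and 8.21 in the AML and LSK Dox groups, and Myc at 4.57 in the AML Dox group.

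By the gene lists fixed before the data were examined, AML cells under Dox had lower transcripts of DNA replication, where 23 of 25 genes fell and 0 rose (Mcm10 -2.70, Cdc45 -3.47, Cdt1 -3.05; 23 adjusted over the list alone). limma's camera gave this list an adjusted p = 4.1e-15 with its preset correlation, and adjusted p = 0.404 with an estimated correlation. Of 24 genes of ribosome biogenesis and Myc targets, 19 fell (Ppan -2.77, Cad -3.02, and Srm again; 22 adjusted over the list alone). Their camera adjusted p was 5.45e-11, or adjusted p = 0.428 with an estimated correlation. Of 24 mitosis genes, 14 fell (Aurkb -2.26, Bub1b -1.80; 18 adjusted over the list alone). Camera's adjusted p was 3.73e-09, or adjusted p = 0.428 with an estimated correlation. Among 15 genes of DNA damage and repair, 13 fell (Fancd2 -2.11, Brca1 -2.53) and 2 rose, also adjusted over the list alone. The camera adjusted p was 3.34e-06, or adjusted p = 0.428 with an estimated correlation. Cyclin-dependent kinase inhibitors, which hold the cell cycle, rose in 4 of 7 genes (Cdkn1b 2.35, Cdkn2c 1.75; 4 adjusted over the list alone). Their camera adjusted p was 0.0132, or adjusted p = 0.372 with an estimated correlation. When LSK compound replicate 1 was left out, 23 of 24 mitosis genes fell and the CDK inhibitors no longer passed camera (adjusted p = 0.0954). The other 4 lists then passed with an estimated correlation (adjusted p = 0.00325 for DNA replication and for DNA damage and repair, adjusted p = 0.000373 for ribosome biogenesis and adjusted p = 0.0124 for mitosis).

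In glycolysis and hypoxia 10 of 16 genes fell in AML cells under Dox (the lactate exporter Slc16a3 -1.98, Ldha -1.37, Vegfa -2.99; 11 adjusted over the list alone). Camera's adjusted p was 6.87e-05, or adjusted p = 0.663 with an estimated correlation. In the unfolded protein and integrated stress response 10 of 20 fell (the serine synthesis enzyme Phgdh -3.45, Chac1 -1.82; 12 adjusted over the list alone). The camera adjusted p was 1.95e-05, or adjusted p = 0.428 with an estimated correlation. In cholesterol synthesis 6 of 15 fell (Insig1 -1.65, Sqle -2.51; 6 adjusted over the list alone). Their camera adjusted p was 0.00244, or adjusted p = 0.704 with an estimated correlation. The interferon response moved the other way: 8 of 17 genes rose and 0 fell (Irf7 4.43, Oas2 3.45; 9 adjusted over the list alone). For this list camera's adjusted p was 0.000244, or adjusted p = 0.663 with an estimated correlation. Of 15 genes of the MLL-AF9 program, the target genes of the fusion, 9 rose and 0 fell (Cpeb2 4.07, Hoxa7 1.20, Hoxa6 1.34, Hoxa9 1.32; 9 adjusted over the list alone). The camera adjusted p was 8.2e-05, or adjusted p = 0.372 with an estimated correlation. Of 17 granule and neutrophil genes, 5 fell (Ctsg, Mpo -3.60, Elane -1.96, Csf3r -2.24) and 1 rose, also adjusted over the list alone. Their camera test gave adjusted p = 0.0338, or adjusted p = 0.372 with an estimated correlation, and did not pass without LSK compound replicate 1 (adjusted p = 0.245). Leaving that array out, 17 of 20 genes of the unfolded protein response and 13 of 15 of cholesterol synthesis fell, and 13 of 17 interferon genes rose. These lists and glycolysis then passed with an estimated correlation (adjusted p = 0.0124, 0.0174, 0.0199 and 0.0197).

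The p53 targets were split in AML cells under Dox: 7 of 21 rose (Trp53inp1 3.39, Btg2 1.33) and 3 fell (Sesn2 -2.13 among them), also adjusted over the list alone (camera adjusted p = 0.299). Of 16 pro-apoptotic genes 2 fell (Bid -2.52, Bcl2l11 -0.75) and 0 rose, and of 10 anti-apoptotic genes 3 rose (Birc3 1.49, Bcl2 0.91) and 2 fell (Birc5 -1.35, Bcl2l1 -0.46). In the pluripotency network 0 of 19 genes rose and 3 fell (Gdf3 -2.62, Klf2 -0.72, Fut4 -0.56). With values under the filter level set to it Fut4 was not called (adjusted p = 0.116). These counts were unchanged adjusted over each list alone. Leaving out LSK compound replicate 1, 1 pro-apoptotic gene rose and 5 fell, 5 anti-apoptotic genes rose and 3 fell, and in the pluripotency network 1 rose and 5 fell.

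In all, limma called 4240 of 16583 genes in AML cells under Dox (2032 higher, 2208 lower), and 2612 of them changed at least 2-fold. The count was 7934 without LSK compound replicate 1, 8025 from the 6 arrays compared alone and 8424 with array quality weights. Camera called 11 lists, or 13 when that array was left out, and 9 of those 13 then passed with an estimated correlation. On simulated data for this comparison, 87.9% of genes set to a log2 change of 2 were called, 38.8% of those set to 1 and 1.49% of those set to 0.5.

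LSK cells under Dox lowered granule and neutrophil genes, and limma called 0 of 24 mitosis genes. The embryonic globin Hbb-y rose from 2.15 ± 0.24 to 8.44 ± 0.30 (SD, n = 3; log2 change 6.29, at least 6.07, SE 0.20, limma adjusted p = 6.55e-11). The fatty acid transporter Cd36 rose by 6.20 (SE 1.14, adjusted p = 0.0041), Akr1c18 by 4.72 (SE 0.20, adjusted p = 1.18e-09), Cd109 by 4.29 (at least 3.76) and the ecto-nucleotidase Nt5e by 4.13. The largest falls were the basophil protease Mcpt8 (-2.68), Ms4a3 (-2.26), myeloperoxidase Mpo (-2.18) and neutrophil elastase Elane (-2.03). Klf4 rose from 3.83 ± 0.12 to 8.21 ± 0.08 (20.8-fold, limma adjusted p = 3.45e-09), while Sox2 (0.30, SE 0.25), Pou5f1 (0.15, SE 0.21) and Myc (-0.60, SE 0.64) did not pass. Myc passed without LSK compound replicate 1 (adjusted p = 0.00469).

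Of 17 granule and neutrophil genes, 9 fell in LSK cells under Dox and 0 rose (Elane, Mpo, Camp -1.31, Ctsg -1.29; 11 adjusted over the list alone). The list passed camera with adjusted p = 3.45e-18, and kept its call at adjusted p = 0.000182 with an estimated correlation. Of 8 mast cell and basophil genes, 2 fell (Mcpt8 and Ms4a2 -0.91; 3 adjusted over the list alone). Their camera adjusted p was 0.000484, or adjusted p = 0.0136 with an estimated correlation. Of 11 mesenchymal genes, 4 rose and 0 fell (fibronectin Fn1 1.93, S100a4 2.16, Sparc 1.73, vimentin Vim 1.08; 4 adjusted over the list alone). Camera's adjusted p was 9.85e-05, or adjusted p = 0.0136 with an estimated correlation. The median of that list was 0.05 and its mean 0.55. Of 21 stem and progenitor genes, 4 rose and 0 fell (the angiopoietin receptor Tek 1.34, Fgd5 1.57, the endothelial protein C receptor Procr 2.78, Mecom 0.95; 6 adjusted over the list alone). The camera adjusted p was 0.00984, or adjusted p = 0.242 with an estimated correlation. On the other 17 arrays, 4 mast cell and basophil genes fell, and 9 stem and progenitor genes rose and 5 fell. The stem and progenitor list then missed camera's threshold (adjusted p = 0.0582), and the mesenchymal list missed it with an estimated correlation (adjusted p = 0.135).

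Several other lists passed camera in LSK cells under Dox on few called members. The reprogramming factors passed on Klf4 (camera adjusted p = 0.00984, or adjusted p = 0.0684 with an estimated correlation). Of 24 genes of ribosome biogenesis and Myc targets 1 fell (Rrp9 -0.57; 1 adjusted over the list alone). Their camera adjusted p was 0.00984, or adjusted p = 0.939 with an estimated correlation. Of 25 DNA replication genes limma called 0 (1 at unadjusted p under 0.05, 0 adjusted over the list alone), with a median of -0.28 and camera adjusted p = 0.0369, or adjusted p = 0.939 with an estimated correlation. Of 21 p53 targets 3 rose (Perp 2.77, Btg2 1.78, Trp53inp1 0.61) and 1 fell (Aen -0.62; 4 and 1 adjusted over the list alone). Camera's adjusted p was 0.0369, or adjusted p = 0.87 with an estimated correlation. Of 17 TGF-beta targets 1 rose (Id3 2.09; 3 and 1 lower adjusted over the list alone). The camera adjusted p was 0.0369, or adjusted p = 0.0991 with an estimated correlation. Of 12 LSD1 and Gfi1 repressed genes 2 fell (Cebpa -0.79, Csf1r -0.89; 3 adjusted over the list alone). Their camera adjusted p was 0.0369, or adjusted p = 0.897 with an estimated correlation. The pluripotency network (19 genes) and mitosis (24 genes) had 0 called genes by limma and 0 at unadjusted p under 0.05. Without LSK compound replicate 1, 20 of 24 ribosome biogenesis genes fell (adjusted p = 0.00297 with an estimated correlation), as did 11 of 25 DNA replication genes and 2 of 24 mitosis genes. Of the p53 targets 5 rose and 3 fell, of the TGF-beta targets 6 rose and 2 fell, and of the LSD1 and Gfi1 repressed genes 2 rose and 6 fell. The TGF-beta targets (adjusted p = 0.0582), the LSD1 list (adjusted p = 0.0934) and the reprogramming factors (adjusted p = 0.0951) then no longer passed camera.

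limma called 602 genes in LSK cells under Dox (477 higher, 125 lower), of which 350 changed at least 2-fold. The count was 3121 (1504 higher, 1617 lower) without LSK compound replicate 1, 2780 from the 6 arrays compared alone, 3601 with array quality weights and 390 to 415 with 1 of those 6 arrays left out. On simulated data for this comparison 89.4% of genes set to a log2 change of 2 were called and 37.3% of those set to 1. The simulation changed only 200 genes, fewer than the 602 called here, so these shares may also be too low.

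The Dox responses of the 2 cell types were compared directly. Lix1 rose by 7.42 more on the log2 scale in AML than in LSK cells (6.85 at the filter level, SE 0.23, limma adjusted p = 7.05e-11; 3 arrays in each of the 4 groups), followed by Matn2 (6.21), the vesicular monoamine transporter Slc18a2 (6.15), Tmem35a (6.02, or 5.68 at that level) and Avil (5.96). Klrb1f (-6.19), Cd36 (-6.04), the phosphodiesterase Pde2a (-5.82), Cd33 (-5.23) and Cd34 (-4.96) had the lowest difference. The log2 difference was 1.49 for Klf4 (SE 0.30, limma adjusted p = 0.00274) and -3.50 for Myc (SE 0.90, adjusted p = 0.016). That of Sox2 (1.01, adjusted p = 0.0807) passed only without LSK compound replicate 1 (adjusted p = 0.0114). That of Pou5f1 (0.52, adjusted p = 0.349) did not pass.

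DNA replication, ribosome biogenesis and mitosis genes had a lower Dox response in AML than in LSK cells. The difference was called lower for 17 of 25 DNA replication genes (Mcm10 -2.42, Cdc45 -3.19; 19 adjusted over the list alone). Camera's adjusted p was 8.07e-14, or adjusted p = 0.651 with an estimated correlation. It was lower for 10 of 24 genes of ribosome biogenesis and Myc targets (Srm -3.94; 14 adjusted over the list alone). The camera adjusted p was 1.33e-08, or adjusted p = 0.651 with an estimated correlation. Lower differences were also called for 8 of 24 mitosis genes (Aurkb -2.26; 13 adjusted over the list alone), with camera adjusted p = 2.47e-09, or adjusted p = 0.651 with an estimated correlation, and for 7 of 15 genes of DNA damage and repair (Fancd2 -2.05; 13 lower and 1 higher adjusted over the list alone), with camera adjusted p = 1.62e-06, or adjusted p = 0.651 with an estimated correlation. For the unfolded protein and integrated stress response it was 9 of 20 (Sesn2 -2.23, Phgdh -2.92; 9 adjusted over the list alone; camera adjusted p = 8.97e-06, or adjusted p = 0.651 with an estimated correlation). For glycolysis and hypoxia it was 5 of 16 (Slc16a3 -2.30; 6 adjusted over the list alone) and for cholesterol synthesis 3 of 15 (Insig1 -1.82; 4 adjusted over the list alone). Both had camera adjusted p = 0.00243, or adjusted p = 0.669 and adjusted p = 0.651 with an estimated correlation. When LSK compound replicate 1 was left out, the difference was lower for 24 ribosome biogenesis, 23 mitosis, 13 damage and repair (1 higher), 16 stress response, 12 glycolysis and 12 cholesterol genes. These 6 lists and DNA replication then passed with an estimated correlation (adjusted p = 0.000314 to adjusted p = 0.0301).

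The difference in Dox response was called higher in AML cells for 6 of 15 genes of the MLL-AF9 program (Cpeb2 3.27, Hoxa7 1.12; 7 adjusted over the list alone), with camera adjusted p = 0.00217, or adjusted p = 0.651 with an estimated correlation. It was higher for 1 of 17 interferon genes (Irf7 4.15; 1 adjusted over the list alone), with camera adjusted p = 0.00338, or adjusted p = 0.669 with an estimated correlation. Leaving out LSK compound replicate 1, 14 of 17 interferon genes were higher (adjusted p = 0.0239 with an estimated correlation), and 8 genes of the MLL-AF9 program were higher and 3 lower. limma called 2227 genes for this difference (1138 higher and 1089 lower in AML cells). There were 6545 without LSK compound replicate 1, 6759 from the arrays compared alone and 7052 with array quality weights. Camera called 9 lists, or 12 when that array was left out, and 9 of those 12 then passed with an estimated correlation.

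The compound mix in AML cells raised monocyte and macrophage genes. The neutrophil chemokine Cxcl3 rose from 1.76 ± 0.24 to 9.55 ± 0.22 (SD, n = 3; log2 change 7.79, at least 7.21, SE 1.21, limma adjusted p = 0.000903), thrombospondin Thbs1 by 7.74 (SE 0.90, adjusted p = 7.08e-05) and the platelet chemokine Ppbp by 7.73 (SE 0.67, adjusted p = 5.36e-06). Gpnmb (5.72), neutrophil collagenase Mmp8 (5.64), Ccl3 (5.56) and versican Vcan (5.07) were among the 10 largest rises. Mpo fell from 10.54 ± 0.01 to 7.27 ± 0.44 (log2 change -3.27, SE 0.22, adjusted p = 4.12e-07), and Clec11a (-3.02), Cd27 (-2.82), Ctsg (-2.10) and Ms4a3 (-2.03) fell as well. Of Pou5f1, Sox2, Klf4 and Myc limma called 0, with 0 at unadjusted p under 0.05, and Myc changed by -0.92 (SE 0.64, adjusted p = 0.646), which passed without LSK compound replicate 1 (adjusted p = 6.08e-05).

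Of 22 monocyte and macrophage genes, 10 rose and 0 fell in AML cells with the compounds: the M-CSF receptor Csf1r rose by 2.79, the transcription factor Irf8 by 1.98, and the Fc receptors Fcgr4 and Fcgr1 by 2.99 and 1.51. Adjusted over the list alone 17 rose. Camera gave adjusted p = 6.16e-19, and the list kept its call at adjusted p = 0.0291 with an estimated correlation. Among 12 LSD1 and Gfi1 repressed genes 3 rose (Csf1r, Irf8, Itgam 3.13) and 1 fell (Cebpa -1.14; 5 and 1 adjusted over the list alone), with camera adjusted p = 7.38e-05, or adjusted p = 0.714 with an estimated correlation. Of 17 NF-kB and inflammatory genes 5 rose (Cxcl2 4.68, Fos 2.46, Ccl4 2.71; 6 adjusted over the list alone), with camera adjusted p = 0.000929, or adjusted p = 0.91 with an estimated correlation. Mitosis fell in 7 of 24 genes (Cdc20 -1.37, Bub1b -0.92; 14 adjusted over the list alone), with camera adjusted p = 6.37e-11, or adjusted p = 0.714 with an estimated correlation. On the other 17 arrays, 19 monocyte genes, 9 LSD1 and Gfi1 repressed genes (1 lower) and 10 NF-kB genes rose, and 24 of 24 mitosis genes fell. All 4 lists then passed with an estimated correlation (adjusted p = 0.00103, 0.00274, 0.00274 and 0.00301).

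In DNA replication 1 of 25 genes fell with the compounds in AML cells (Mcm10 -0.70; 1 adjusted over the list alone), with a median of -0.62 and camera adjusted p = 4.37e-05, or adjusted p = 0.91 with an estimated correlation. Ribosome biogenesis and Myc targets had a median of -0.47 with 0 of 24 genes called by limma (3 at unadjusted p under 0.05, 0 adjusted over the list alone), camera adjusted p = 0.0288, or adjusted p = 0.91 with an estimated correlation. Of 17 interferon genes 1 rose (Usp18 4.19; 1 adjusted over the list alone; camera adjusted p = 0.0136, or adjusted p = 0.91 with an estimated correlation). Of 17 genes of lysosome and autophagy 1 rose (cathepsin L, Ctsl, 3.67) and 1 fell (Ulk1 -0.80), also adjusted over the list alone (camera adjusted p = 0.0288, or adjusted p = 0.91 with an estimated correlation). Of 7 CDK inhibitors 1 rose (Cdkn2c 1.27; 1 adjusted over the list alone; camera adjusted p = 0.0282, or adjusted p = 0.258 with an estimated correlation). Of 21 p53 targets 3 rose (Trp53inp1 1.28, Pmaip1 1.40, Btg2 0.69; 3 and 1 lower adjusted over the list alone), with camera adjusted p = 0.0441, or adjusted p = 0.91 with an estimated correlation. The MLL-AF9 program changed in 1 of 15 genes (Mef2c 1.48; 1 adjusted over the list alone; camera adjusted p = 0.64). Without LSK compound replicate 1, 22 DNA replication and 21 ribosome biogenesis genes fell, and 10 interferon and 12 lysosome genes rose (1 lysosome gene fell). These 4 lists then passed with an estimated correlation (adjusted p = 0.0073, 0.00274, 0.0332 and 0.0012). Of the CDK inhibitors 4 rose, of the p53 targets 7 rose and 1 fell, and of the MLL-AF9 program 3 rose and 6 fell.

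limma called 1064 genes in AML cells with the compounds (525 higher, 539 lower), 475 of them at 2-fold or more (332 higher, 143 lower, and 559 and 178 without LSK compound replicate 1). With each array centred on its median the split was 488 higher and 877 lower. The count was 5226 (2087 higher, 3139 lower) without LSK compound replicate 1, 4475 from the 6 arrays compared alone, 5816 with array quality weights and 670 to 773 with 1 of those 6 arrays left out. Camera called 10 lists, and 6 without AML compound replicate 1 or with a stricter filter on dim probe sets. It called 13 without LSK compound replicate 1, of which 8 passed with an estimated correlation.

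The compound mix in LSK cells raised inflammatory and interferon genes and lowered mitosis and granule genes, in a group that includes LSK compound replicate 1 and the sex-linked transcripts described above. The cyclooxygenase Ptgs2 rose by 5.58 (SE 1.01, limma adjusted p = 0.00165; from 3.81 ± 0.24 to 9.39 ± 3.33, SD, n = 3), and by 7.50 without that array. The chemokine Cxcl10 rose by 5.38 (7.81 without it), interleukin 6 (Il6) by 4.39 (at least 4.23; 6.39 without it), Cxcl9 by 4.25 (at least 4.17; 5.88 without it) and the guanylate-binding protein Gbp10 by 4.38 (5.28). Mpo fell from 9.16 ± 0.28 to 4.20 ± 0.24 (log2 change -4.96, SE 0.22, adjusted p = 2.68e-09), and Bex6 (-5.22, or -4.87 at the filter level), Chil3 (-5.14; -4.54 without that array), Ctsg (-4.62) and Elane (-4.46) also fell. Klf4 rose by 1.38 (SE 0.21, adjusted p = 0.000399; 1.07 without that array). Myc fell from 9.34 ± 0.13 to 7.34 ± 2.06 (SE of the change 0.64, limma adjusted p = 0.0424). Without that array its log2 change was -0.81 (adjusted p = 0.000434).

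All 24 mitosis genes tested fell in LSK cells with the compounds (Bub1b -2.30, Cenpf -2.07, Aurka -2.10; 24 adjusted over the list alone, and 24 without that array). Camera gave adjusted p = 7.84e-24, or adjusted p = 0.282 with an estimated correlation. Of 17 granule and neutrophil genes 13 fell and 0 rose (Elane, Ctsg, Mpo, Camp -2.51; 13 adjusted over the list alone), with camera adjusted p = 6.81e-13, and the list kept its call at adjusted p = 0.00111 with an estimated correlation. Of 17 NF-kB and inflammatory genes 10 rose and 0 fell (the NF-kB inhibitor Nfkbia 2.35, Cd83 1.71, Ccl4 3.94; 13 adjusted over the list alone), with camera adjusted p = 9.04e-10, or adjusted p = 0.348 with an estimated correlation. Of 17 interferon genes 10 rose and 0 fell (Mx2 1.88, Oas2 2.38, Rsad2 3.51; 12 adjusted over the list alone), with camera adjusted p = 4.38e-07, or adjusted p = 0.526 with an estimated correlation. Without that array 16 of 17 rose in both lists (Ccl4 5.10, Oas2 3.17, Rsad2 5.05), and both passed with an estimated correlation (adjusted p = 5.96e-05 and adjusted p = 0.00109).

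Of 25 DNA replication genes 21 fell in LSK cells with the compounds (Mcm10 -1.64, Rrm2 -2.38; 24 adjusted over the list alone), with camera adjusted p = 4.16e-10, or adjusted p = 0.526 with an estimated correlation. Their median was -1.64, and without that array -0.89 (Rrm2 -1.64). Of 24 genes of ribosome biogenesis and Myc targets 8 fell (Cad -1.69; 23 adjusted over the list alone), with camera adjusted p = 3.92e-06, or adjusted p = 0.577 with an estimated correlation. Their median moved from -1.65 to -0.55 without it (Cad -1.03). Of 15 genes of DNA damage and repair 10 fell (Fancd2 -2.07) and 1 rose (12 and 1 adjusted over the list alone), with camera adjusted p = 1.52e-05, or adjusted p = 0.526 with an estimated correlation. Of 22 chromatin regulators 7 fell (the maintenance methylation factor Uhrf1 -1.76, the methyltransferase Dnmt3b -1.59) and 1 rose (9 and 1 adjusted over the list alone), with camera adjusted p = 0.00529, or adjusted p = 0.526 with an estimated correlation. Of 12 dendritic and antigen presentation genes 5 rose (Cd83, Ciita 1.89, Ccr7 1.99) and 1 fell (Flt3 -2.55; 5 and 1 adjusted over the list alone), with camera adjusted p = 0.0235, or adjusted p = 0.526 with an estimated correlation. Of 9 B cell genes 3 rose (Blnk 1.80, Ebf1 1.21, Igll1 1.25; 3 adjusted over the list alone), with camera adjusted p = 0.0235, or adjusted p = 0.328 with an estimated correlation. Of 15 Wnt and beta-catenin targets 2 rose (Apcdd1 1.09, Nkd1 1.43) and 1 fell (Ccnd1 -0.81), also adjusted over the list alone, with camera adjusted p = 0.0377, or adjusted p = 0.569 with an estimated correlation. Without that array the change was 2.73 for Ccr7 and -1.81 for Flt3, 20 ribosome biogenesis genes fell and 1 rose, and the Wnt targets (adjusted p = 0.386) and B cell genes (adjusted p = 0.194; 3 higher, 2 lower) no longer passed camera.

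limma called 2925 genes in LSK cells with the compounds (813 higher, 2112 lower), 1510 of them at 2-fold or more (400 higher, 1110 lower). When LSK compound replicate 1 was left out, that split turned, with 889 higher and 533 lower. The count was 5579 (2319 higher, 3260 lower) without LSK compound replicate 1, and 2864 genes were called in the same direction both ways. Camera called 11 lists, or 14 without that array, of which 10 passed with an estimated correlation. The gene count was 61 from the 6 arrays compared alone, 5271 and 5913 without LSK compound replicate 2 and 3, and 1781, 1833 and 1665 without LSK control replicate 1, 2 and 3.

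The compound responses of the 2 cell types differed in granule genes. The test of the difference was higher in AML cells for 11 of 17 granule and neutrophil genes and lower for 0 (Elane 3.95, Ctsg 2.52, Camp 2.33, Chil3 4.84; 15 adjusted over the list alone), with camera adjusted p = 4.44e-22 and adjusted p = 6.68e-05 with an estimated correlation. In AML control 5 of these genes (Chil3, Camp, S100a9, Ltf, Fcnb) lay under the filter level and had little room to fall, so for Chil3 the difference is the fall in LSK cells. Of the other 12 genes, a choice made after the data were seen, 7 were higher and 0 lower (camera adjusted p = 2.05e-15, and adjusted p = 0.00106 with an estimated correlation). Thbs1 (5.54, SE 1.28, limma adjusted p = 0.0254), Gpnmb (5.44), Clec12a (5.02) and Ppbp (4.79) had the other largest positive differences, and the integrin Itgb8 (-3.52; -3.19 and not called at the filter level, adjusted p = 0.0723), Lad1 (-3.40), the serotonin receptor Htr7 (-3.24), Traf1 (-3.15) and Olfm5 (-3.14) the largest negative ones. Leaving out LSK compound replicate 1, Clec12a had the largest of these positive differences (4.89). Chil3, Thbs1, Gpnmb and Ppbp (3.54 to 4.24) were lower than with it. The negative ones were then larger in size (-4.70 to -4.12). The Klf4 response was lower in AML cells (-1.21, SE 0.30, limma adjusted p = 0.0358). For Myc the difference was 1.09 (SE 0.90, adjusted p = 0.549) and -0.10 without LSK compound replicate 1, uncalled both ways.

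Mitosis genes fell less with the compounds in AML cells than in LSK cells: the difference was higher for 11 of 24 (Kif23 2.94, Cenpf 1.48; 24 adjusted over the list alone), with camera adjusted p = 1.18e-19, or adjusted p = 0.238 with an estimated correlation. It was higher for 6 of 22 monocyte and macrophage genes (Csf1r 3.39, Ccr2 2.85) and lower for 1 (9 and 1 adjusted over the list alone), with camera adjusted p = 1.45e-06, or adjusted p = 0.238 with an estimated correlation. For LSD1 and Gfi1 repressed genes it was higher in 3 of 12 (Csf1r, Irf8 2.13, Itgam 3.96; 4 adjusted over the list alone; camera adjusted p = 0.000163, or adjusted p = 0.437 with an estimated correlation), and for DNA damage and repair in 2 of 15 (Fancd2 1.35, Chek2 1.86; 5 adjusted over the list alone; camera adjusted p = 7.61e-06, or adjusted p = 0.437 with an estimated correlation). It was lower for 4 of 17 NF-kB and inflammatory genes (Cd83 -1.90, Nfkbia -1.55; 4 adjusted over the list alone), with camera adjusted p = 6.35e-05, or adjusted p = 0.439 with an estimated correlation, and for 1 of 17 interferon genes (Mx2 -1.84; 1 adjusted over the list alone), with camera adjusted p = 0.000873, or adjusted p = 0.589 with an estimated correlation. On the other 17 arrays, the difference was higher for 24 mitosis (Kif23 2.30), 13 monocyte (6 lower), 5 LSD1 and Gfi1 repressed (Itgam 2.80; 3 lower) and 8 damage and repair genes (1 lower). It was lower for 14 NF-kB genes (2 higher) and 14 interferon genes. Mitosis, damage and repair, NF-kB and interferon genes then passed with an estimated correlation (adjusted p = 0.000839, 0.0135, 0.000134 and 0.00112).

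B cell genes had a lower compound response in AML cells in 3 of 9 genes (Ebf1 -1.23, Blnk -1.75, Igll1 -1.33; 3 adjusted over the list alone), with camera adjusted p = 0.00148, or adjusted p = 0.123 with an estimated correlation. For DNA replication the difference was higher in 1 of 25 genes (Mcm10 0.94; 1 adjusted over the list alone), with camera adjusted p = 9.15e-05, or adjusted p = 0.589 with an estimated correlation. The mitochondrially encoded genes passed camera (adjusted p = 0.0303, or adjusted p = 0.617 with an estimated correlation) with 0 of 10 genes called by limma and 0 at unadjusted p under 0.05. Their median difference was 2.76 with LSK compound replicate 1 and 0.11 without it. For ribosome biogenesis and Myc targets there were 0 of 24 genes called (1 at unadjusted p under 0.05), a median of 1.03 and 0.10, and camera adjusted p = 0.00344, or adjusted p = 0.617 with an estimated correlation. Neither passed camera without that array (adjusted p = 0.184 and adjusted p = 0.715), and 5 DNA replication genes were then higher. limma called 520 genes for this difference (389 higher, 131 lower in AML cells), a split that was 341 and 193 with each array centred on its median and 322 and 181 after quantile normalization. There were 2782 (1415 higher, 1367 lower) without LSK compound replicate 1 and 214 from the arrays compared alone, and camera called 11 lists, or 18 without LSK compound replicate 2. Without replicate 1 it called 15, of which 7 passed with an estimated correlation.

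Untreated AML cells had lower stem and progenitor genes than LSK cells, and granule genes were split. The prostaglandin-degrading enzyme Hpgd was 8.12 higher in AML cells (10.49 ± 0.12 against 2.37 ± 0.48, SD, n = 3; SE 0.29, limma adjusted p = 1.34e-10), followed by the ephrin receptor Epha7 (6.14) and Slfn4 (4.88). Lower in AML cells were Xist (-6.94, SE 0.79, adjusted p = 2.81e-05), carbonic anhydrase Car2 (-6.18), Chil3 (-6.05, or -5.70 at the filter level) and the calprotectin subunit S100a8 (-5.66). In the MLL-AF9 program 8 of 15 genes were higher (Hoxa5 3.41, Hoxa6 2.97, Hoxa7 1.57) and 3 lower (Mef2c -2.48), also adjusted over the list alone, with camera adjusted p = 1.73e-05, or adjusted p = 0.0827 with an estimated correlation.

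Stem and progenitor genes were lower in untreated AML than LSK cells in 8 of 21 (Hlf -1.48, the cytokine receptor Flt3 -4.09) and higher in 0 (9 lower and 1 higher adjusted over the list alone), with camera adjusted p = 1.08e-06 and adjusted p = 0.0242 with an estimated correlation. Granule and neutrophil genes were lower in 8 of 17 (Camp -2.82, Ngp -4.66, Chil3) and higher in 4 (Ctsg 2.20, and, chosen after their values were seen, Mpo 1.38, Prtn3 0.95 and Cebpe 0.91; 10 and 4 adjusted over the list alone), with camera adjusted p = 5.17e-05 and adjusted p = 0.0242 with an estimated correlation. Lower too were 4 of 11 megakaryocyte and platelet genes (Itgb3 -1.92, Itga2b -0.97; 4 and 1 higher adjusted over the list alone), with camera adjusted p = 0.00295 and adjusted p = 0.0321 with an estimated correlation, and 5 of 17 TGF-beta targets with 1 higher (Tgfbi -3.12, Pmepa1 -1.53, Id1 1.07; 7 and 2 adjusted over the list alone), with camera adjusted p = 0.000504 and adjusted p = 0.0242 with an estimated correlation. Monocyte and macrophage genes were lower in 6 of 22 (Csf1r -2.10, Irf8 -1.47) and higher in 1 (7 and 1 adjusted over the list alone), with camera adjusted p = 0.000724, or adjusted p = 0.316 with an estimated correlation. Once LSK compound replicate 1 was left out, 14 stem and progenitor (2 higher), 11 granule (5 higher), 7 megakaryocyte (1 higher), 8 TGF-beta (2 higher) and 12 monocyte genes (3 higher) were lower.

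Another 5 lists passed camera between the untreated cell types with calls lost under an estimated correlation. Mesenchymal genes were lower in 4 of 11 (S100a4 -2.59; 4 and 1 higher adjusted over the list alone; camera adjusted p = 0.00582, or adjusted p = 0.0577 with an estimated correlation), dendritic and antigen presentation genes in 1 of 12 (Flt3; 3 adjusted over the list alone; camera adjusted p = 0.00594, or adjusted p = 0.319 with an estimated correlation), and B cell genes in 2 of 9 (Dntt -1.07, Cd79b -0.98; 2 adjusted over the list alone; camera adjusted p = 0.035, or adjusted p = 0.169 with an estimated correlation). Mast cell and basophil genes were lower in 3 of 8 (Mcpt8 -1.98) and higher in 1 (Hdc 1.22), also adjusted over the list alone (camera adjusted p = 0.00683, or adjusted p = 0.0536 with an estimated correlation). The unfolded protein and integrated stress response was higher in 3 of 20 (Chac1 1.40, Atf5 1.04, Sesn2 1.10; 5 adjusted over the list alone; camera adjusted p = 0.0012, or adjusted p = 0.575 with an estimated correlation). When LSK compound replicate 1 was left out, 6 dendritic and 4 B cell genes were lower and 13 stress response genes higher (1 lower), and 8 of the 16 lists that camera then called passed with an estimated correlation. limma called 1433 genes between the untreated cells (685 higher, 748 lower in AML cells), 766 at 2-fold or more. With each array centred on its median 1014 were higher and 622 lower. The count was 4819 without LSK compound replicate 1, 4828 from the 6 arrays compared alone and 5522 with array quality weights. Cell source, sex-linked transcripts and leukemia cannot be separated in this comparison.

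The 2 treatments were compared directly within AML cells. Akr1c18 (8.49, SE 0.20, limma adjusted p = 3.8e-13), Lix1 (7.25, at least 6.84), Avil (6.29) and Klf4 (5.70, SE 0.21, adjusted p = 4.63e-11) were higher under Dox, and Ppbp (-7.88, SE 0.67, adjusted p = 3.89e-07), Cxcl3 (-7.83, or -7.16 at the filter level), Thbs1 (-7.25), the myeloid receptor Cd33 (-7.11) and Lilrb4a (-6.86) higher with the compounds. Under Dox 20 of 25 DNA replication genes were lower than with the compounds (Mcm10 -1.99; 22 adjusted over the list alone), with camera adjusted p = 1e-11, or adjusted p = 0.408 with an estimated correlation. So were 16 of 24 genes of ribosome biogenesis and Myc targets (Srm -4.05; 17 adjusted over the list alone), with camera adjusted p = 3.48e-09, or adjusted p = 0.424 with an estimated correlation. LSD1 and Gfi1 repressed genes were lower under Dox in 8 of 12 (Csf1r -3.09, Irf8 -2.61; 8 adjusted over the list alone), with camera adjusted p = 2.13e-05, or adjusted p = 0.408 with an estimated correlation. Monocyte and macrophage genes were lower in 11 of 22 and higher in 2 (Vcam1 4.88 and Klf4; 13 and 2 adjusted over the list alone), with camera adjusted p = 0.000164, or adjusted p = 0.408 with an estimated correlation. limma called 3888 genes (2039 higher and 1849 lower under Dox), 2322 of them at 2-fold or more, and 14 lists passed camera, 0 of them with an estimated correlation. The gene count was 7799 without LSK compound replicate 1, 7261 from the 6 arrays compared alone and 8191 with array quality weights. When that array was left out camera called 15 lists, and 10 of those passed with an estimated correlation.

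Within LSK cells, Klrb1f, a lectin-like receptor gene (7.17, SE 0.17, limma adjusted p = 8.75e-13), Hbb-y (6.02, at least 5.84, SE 0.20, adjusted p = 8.25e-11), Ceacam1 (5.74, or 5.08 without LSK compound replicate 1) and Akr1c18 (4.97) were higher under Dox than with the compounds. Cxcl10 (-5.85, or -8.28 without that array), Ptgs2 (-5.32, or -7.24) and the interleukin 1 genes Il1a (-4.90, or -7.48) and Il1b (-4.85, or -7.48) were lower. All 24 mitosis genes were higher under Dox (Cenpf 2.12, Bub1b 2.05; 24 adjusted over the list alone), with camera adjusted p = 5.84e-23, or adjusted p = 0.156 with an estimated correlation. NF-kB and inflammatory genes were lower in 11 of 17 (Cd83 -1.79, Nfkbia -1.61; 15 adjusted over the list alone), with camera adjusted p = 4.91e-09, or adjusted p = 0.319 with an estimated correlation. TGF-beta targets were higher in 9 of 17 (Ski 2.04, Skil 2.34, Id1 1.49) and lower in 1 (9 and 2 adjusted over the list alone), with camera adjusted p = 0.00478, or adjusted p = 0.0752 with an estimated correlation. limma called 2547 genes (1820 higher and 727 lower under Dox, or 1479 and 968 after quantile normalization), 1375 at 2-fold or more (1034 higher and 341 lower, or 719 and 819 without that array), and 15 lists passed camera, 0 of them with an estimated correlation. Camera called 16 lists without LSK compound replicate 1, and 14 of those passed with an estimated correlation. The gene count was 5282 (2933 higher, 2349 lower) without LSK compound replicate 1, 5199 and 6120 without replicate 2 and 3 of that group, 1628, 1598 and 1680 without LSK Dox replicate 1, 2 and 3, and 253 from the 6 arrays compared alone.

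Responses were also compared across genes, which are not independent replicates. The Dox responses of AML and LSK cells correlated at r = 0.363 (rho = 0.376) and the compound responses at r = 0.422 (rho = 0.403), or 0.555 without LSK compound replicate 1, and 233 genes rose and 62 fell in both under Dox (58.4 and 16.6 for independent lists of these sizes). With the compounds 157 genes rose and 367 fell in both cell types (25.7 and 68.6 for independent lists). Leaving out LSK compound replicate 1, the shared genes were 849 higher and 1088 lower under Dox (340 and 408 for independent lists), and 1106 and 1936 with the compounds (292 and 617). The Dox and compound responses of one cell type share their control arrays, so they correlate with no effect at all. In AML cells they correlated at r = 0.338 (rho = 0.404) with a covariance of 0.161, and simulated unchanged groups gave r = 0.50 and a covariance of 0.0589, a difference in covariance of 0.103. In LSK cells the values were r = 0.238 (rho = 0.285) and a covariance of 0.0797, against simulated values of r = 0.502 and 0.0589, a difference of 0.0208. Without that array the simulated covariances were 0.00915 and 0.00913, and the differences 0.152 in AML and 0.0657 in LSK cells. In AML cells 209 genes rose and 336 fell with both treatments (64.3 and 71.8 for independent lists), and in LSK cells 88 rose and 94 fell (23.4 and 15.9). Genes called in opposite directions were 58 higher and 49 lower under Dox in AML cells, and 62 and 1 in LSK cells. Without that array 1035 rose and 2062 fell with both in AML cells (472 and 791 for independent lists), and 588 and 910 in LSK cells (210 and 318). The opposite counts were then 488 and 380 in AML cells and 231 and 192 in LSK cells. With 3 controls no split leaves 2 on each side, so part of the excess may come from the shared controls.

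**Figure D3:**
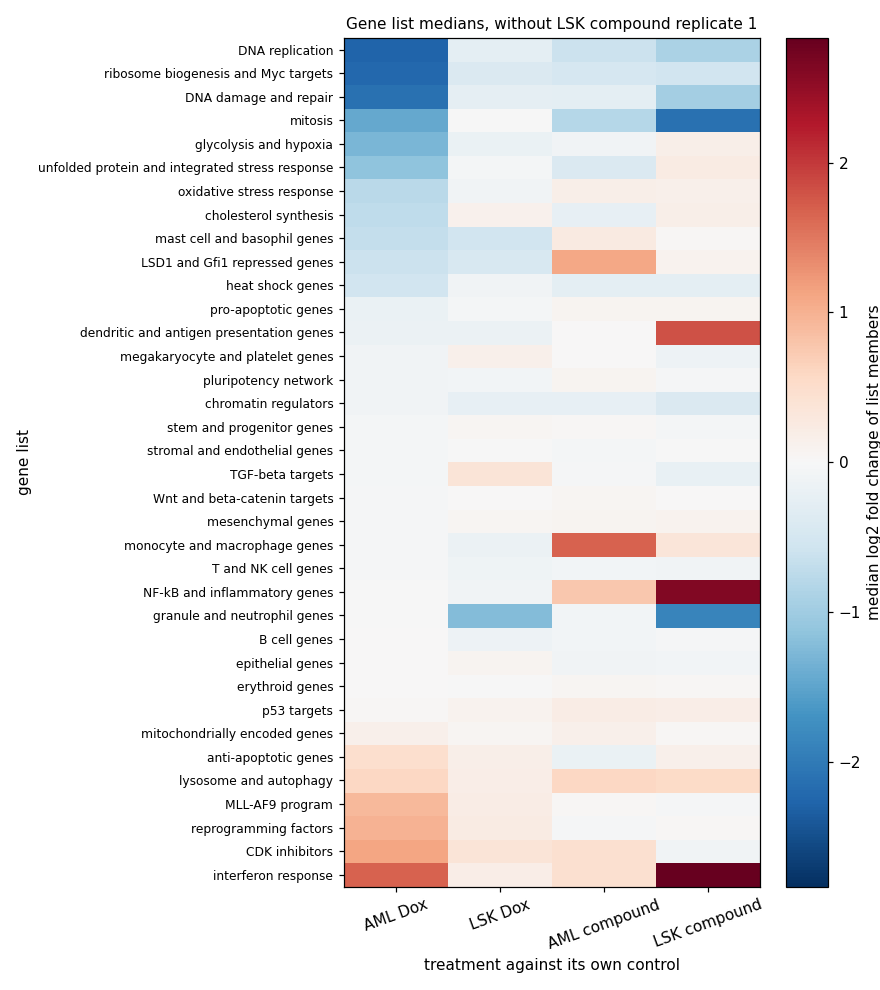
Median log2 fold change (color) over the tested members of each of 36 gene lists, for each treatment against its own control, without LSK compound replicate 1. DNA replication has a median of -2.27 in AML cells under Dox, and NF-kB and inflammatory genes a median of 2.62 in LSK cells with the compounds.

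Of the 36 lists, 11 passed camera for none of the 4 treatment effects. The lowest camera adjusted p among the 4 was 0.0813 for the pluripotency network, 0.0551 for epithelial genes, 0.354 for pro-apoptotic and 0.585 for anti-apoptotic genes, 0.309 for erythroid, 0.316 for megakaryocyte and platelet, 0.378 for T and NK cell and 0.0888 for stromal and endothelial genes. It was 0.0646 for both the oxidative stress response and heat shock genes, and 0.0536 for mitochondrially encoded genes. On the other 17 arrays, the oxidative stress (adjusted p = 0.000447) and heat shock lists (adjusted p = 0.00259) passed camera for AML Dox, pro-apoptotic genes for LSK compound (adjusted p = 0.0427) and mitochondrially encoded genes for AML compound (adjusted p = 0.0452). None of the 4 passed with an estimated correlation. The desmosomal gene Dsp, of the epithelial list, rose by 2.05 in AML and 2.19 in LSK cells under Dox. The stromal genes Dcn (2.41, or 1.997 at the filter level) and Sparc (1.73) rose in LSK cells under Dox, where 2 of the 12 genes of that list were called, also adjusted over the list alone. In AML cells under Dox the transferrin receptor gene Tfrc fell (log2 change -3.70), as did 4 of 13 oxidative stress genes (Gclc -1.88, Srxn1 -1.21; 4 adjusted over the list alone) and 3 of 12 heat shock genes (Hsph1 -3.16; 4 adjusted over the list alone). Without that array 11 oxidative stress genes fell and 1 rose, and 8 heat shock genes fell. Of the 10 mitochondrially encoded genes limma called 0 for each treatment, with 0 at unadjusted p under 0.05. Monocyte and macrophage genes in LSK cells with the compounds had a median of -0.05 but a mean of 0.40, with 8 of 22 higher and 3 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.309). Their median was 0.34 without LSK compound replicate 1, with camera adjusted p = 0.000543, or adjusted p = 0.0597 with an estimated correlation.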

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

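The tests of LSK compound replicate 1, of the sex-linked transcripts (apart from the correlation of the AML and LSK compound responses) and of the AML and LSK Dox responses (apart from array scaling) were chosen only after the results were seen.

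The first pattern is LSK compound replicate 1. Of the 500 genes brightest on the other 17 arrays, 93.2% lay below the lowest of those arrays, which is the pattern itself and tests no explanation. A mislabelled array of another group would read within the range of the other 17 in these genes. Only 3.8% did, so the pattern itself argues against a swap within the series. The same genes had a median difference of -3.43 from LSK compound replicates 2 and 3, which restates the pattern. Failed labelling or hybridization, degraded or insufficient RNA, and RNA of another cell type mixed in stay open, since no value here parts them. No biological explanation was tested.

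The second pattern is that LSK compound replicates 2 and 3 held both Xist and Y-linked transcripts. The Y-linked genes lay a median of 3.41 above LSK control, which is the pattern itself and tests no explanation. The AML controls lay only 0.244 above the LSK controls in these genes, which argues against RNA of the AML samples. The LSK compound response without replicate 1 correlated at 0.555 with the AML compound response across genes, which argues against other animals as the whole cause of it. LSK control and Dox arrays held Xist but no Y-linked transcripts (at most 2.14), which is the pattern again and tests no cause. Other animals and the treatment stay open, and their effects on other genes cannot be parted.

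The third pattern is that Dox changed more genes in AML than in LSK cells, 4240 against 602, or 7934 against 3121 without LSK compound replicate 1. After quantile normalization the ratio of the counts was 7.19, or 2.49 without that array, which argues against array scaling. Of the genes changed 2-fold in LSK cells without LSK compound replicate 1, 58.6% had a called difference with the larger change in LSK cells, which argues against the LSK response being only a weaker copy. Of the B cell, T and NK cell, erythroid, megakaryocyte, mast cell and stromal lists, the highest median under Dox in AML cells was 0.0117, which argues against such cells mixed in. A difference between the leukemia and the normal cells in their response to the factors may remain, and unequal transgene expression stays open and was not tested.

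Responses that differed between AML and LSK cells by limma's test of the difference itself were 2227 genes for Dox and 520 for the compounds, and 9 and 11 lists by camera. For Dox, the log2 difference (AML less LSK) was 7.42 for Lix1, 6.21 for Matn2, 6.15 for Slc18a2, 6.02 for Tmem35a, 5.96 for Avil, -6.19 for Klrb1f, -6.04 for Cd36, -5.82 for Pde2a, -5.23 for Cd33 and -4.96 for Cd34. With compounds it was 5.54 (Thbs1), 5.44 (Gpnmb), 5.02 (Clec12a), 4.84 (Chil3), 4.79 (Ppbp), -3.52 (Itgb8), -3.40 (Lad1), -3.24 (Htr7), -3.15 (Traf1) and -3.14 (Olfm5). Without LSK compound replicate 1 these 10 were, in order, 3.85, 3.83, 4.89, 4.24, 3.54, -4.70, -4.33, -4.197, -4.13 and -4.12.

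A signal also lay in probe sets not paired with 1 gene, which the comparisons of genes leave out. Of 11675 such probe sets among 29215 tested, limma called 1635 for AML Dox, 81 for LSK Dox, 243 for AML compound and 602 for LSK compound, each against its control. Without LSK compound replicate 1 it called 3269, 522, 1417 and 1445.

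Regrouping the arrays tested whether chance splits give results as large. For the comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real count of genes and the highest of the other splits were 4240 and 0 for AML Dox, 602 and 0 for LSK Dox, 1064 and 0 for AML compound, 2925 and 1 for LSK compound, 1433 and 0 for the controls, 3888 and 0 for Dox against compound in AML cells, and 2547 and 0 in LSK cells, with 1 of 10 splits as large in each case, the real one included. For lists the real count, the highest other and the number of the 10 splits as large were 11, 11 and 3 for AML Dox, 10, 4 and 1 for LSK Dox, 10, 6 and 1 for AML compound, 11, 17 and 10 for LSK compound, 11, 5 and 1 for the controls, 14, 12 and 1 for Dox against compound in AML cells, and 15, 18 and 9 in LSK cells. Counts of lists by camera at the preset correlation are therefore weak evidence.

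For the differences between responses, 100 of 200 splits were drawn. As many genes as the real count were called in 8 of them for Dox (real 2227, highest other 3631) and 7 for the compounds (real 520, highest other 3268), the real one included. The 7 and 6 other splits as large all kept the real groups of at least 1 cell type, and the 78 and 82 drawn splits that kept neither called at most 0 genes. For lists, 55 splits were as large for Dox (real 9, highest other 15) and 94 for the compounds (real 11, highest other 19), so chance is not excluded there.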

How the results depend on the processing

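The fits without LSK compound replicate 1 in comparisons that do not use its group, and those with values under the filter level set to it, were chosen only after the results were seen. Of 431 named results, 410 were called with all 18 arrays. None of these (0) lost the call without LSK compound replicate 1, and 72 lost it in at least 1 fit without another array. In single fits 101 lost it from the groups compared alone, 53 with quantile normalization, 23 over all probe sets, 8 with no filter, 4 with centring and 3 with values under the filter level set to it, which moved no count of genes by over 1.5 times. Signal over background limits the dim genes: Pou5f1 and Sox2, in groups with means of at most 3.18, account for most of the reversals. The causes of the changes listed here were not tested, except that fits with fewer arrays have fewer degrees of freedom.

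The replicate numbers do not pair the arrays: same-numbered arrays correlated at -0.28 to 0.26 in their deviations from the group means, and 2 of 45 pairs were over 0.1. With the replicate block limma called 4128 genes for AML Dox, 534 for LSK Dox, 957 for AML compound, 2737 for LSK compound, 2085 and 464 for the differences in Dox and compound response, 1331 for the controls, and 3788 and 2412 for Dox against compound in AML and LSK cells. The block cost 10 named results their call, and changed no other named call, nor any count of genes or lists by over 1.5 times.

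Leaving out 1 array in turn gave 3479 to 7934 genes for AML Dox, 390 to 3121 for LSK Dox, 670 to 5226 for AML compound, 1665 to 5913 for LSK compound, 1769 to 6545 and 353 to 2782 for the differences in Dox and compound response, 999 to 4819 for the controls, and 3098 to 7799 and 1598 to 6120 for Dox against compound in AML and LSK cells. The highest was without LSK compound replicate 1, or, for LSK compound and LSK Dox against compound, without replicate 3 of that group. In the same order, lists numbered 11 to 13, 7 to 12, 6 to 13, 10 to 14, 9 to 12, 10 to 18, 10 to 16, 14 to 15 and 12 to 17. The correlation of AML with LSK responses was 0.310 to 0.555 for the compounds and 0.354 to 0.363 for Dox, and that of Dox with compound responses 0.331 to 0.345 in AML and 0.198 to 0.261 in LSK cells.

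In the same order of comparisons, the groups compared alone gave 8025, 2780, 4475, 61, 6759, 214, 4828, 7261 and 253 genes, and array quality weights 8424, 3601, 5816, 8685, 7052, 4784, 5522, 8191 and 8641, with LSK compound replicate 1 at a weight of 0.00627. A fold of at least 2 left 2612, 350, 475 and 1510 genes for the 4 treatment effects, 766 for the controls, and 2322 and 1375 for Dox against compound. An estimated correlation left 0, 3, 1, 1, 0, 1, 4, 0 and 0 lists, and the stricter filter 6 for AML compound. The correlation of AML with LSK Dox responses was 0.354 after quantile normalization, 0.376 with the stricter filter and 0.343 over all probe sets. That of Dox with compound responses in AML cells was 0.312 after quantile normalization and 0.307, 0.309 and 0.310 with split controls, and in LSK cells 0.177 with the compound set against control 3 alone.

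Centring each array on its median moved the median change of all genes from 0.00 to 0.12 between the controls. Signs reversed for 7 results with 1 array left out. For Pou5f1 the range was -0.0036 to 0.33 in LSK Dox (below 0 without LSK Dox replicate 2), -0.070 to 0.051 in AML compound (AML control 1 and AML compound 3, -0.063), -0.15 to 0.0023 between the controls (AML control 1), and -0.24 to 0.15 in LSK Dox against compound (LSK compound 1, and LSK Dox 1, 0.13). For Sox2 it was -0.19 to 0.013 in AML compound (AML compound 1) and -0.19 to 0.22 in LSK Dox against compound (LSK Dox 3, and LSK compound 2 and 3, -0.026 and -0.12). The difference in compound response of Myc was -0.10 to 1.68, lowest without LSK compound replicate 1. With centring, Pou5f1 was -0.081 in AML compound and 0.052 between the controls, and Sox2 -0.052 in LSK Dox against compound. With quantile normalization, Pou5f1 was -0.043 in AML compound, 0.0030 between the controls and 0.11 in LSK Dox against compound. Kdm1a, called lower in LSK compound at -0.67 (adjusted p = 0.00272), was 0.023 with quantile normalization and no longer called.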

Other observations

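The test of erythroid differentiation was chosen only after the rise of Hbb-y was seen.

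Under Dox, AML cells changed regulators of chromatin in both directions. Of 22 genes of the chromatin list limma called 5 higher and 4 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.989). The histone demethylase genes Kdm5b and Kdm1a rose by 2.35 and 0.71, and the maintenance methylation factor Uhrf1 fell (log2 change -3.38). Of 21 stem and progenitor genes, Mllt3 rose (2.28), Kit (-2.78) and Cd34 fell, and the others did not pass (camera adjusted p = 0.942). Without LSK compound replicate 1 limma called 9 chromatin genes higher and 10 lower, and 6 stem and progenitor genes higher and 7 lower, and neither list passed camera (adjusted p = 0.82 and adjusted p = 0.655). In LSK cells with the compounds, 6 of 17 TGF-beta targets fell (Tgfbi -2.84, Ski -1.47) and 1 rose (7 and 2 adjusted over the list alone), with camera adjusted p = 0.0959. Of 17 lysosome and autophagy genes limma called 1 higher and 1 lower there, and without LSK compound replicate 1 it called 10 higher and 3 lower, with camera adjusted p = 6.11e-05 and adjusted p = 0.0045 with an estimated correlation.

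Hbb-y, an embryonic beta-like globin gene chosen in AML cells after its values were seen, rose under Dox from 2.17 ± 0.10 to 7.63 ± 0.30 in AML cells (SD, n = 3; log2 change 5.45, SE 0.20, limma adjusted p = 4.04e-11) and by 6.29 in LSK cells (limma adjusted p = 6.55e-11), with 3 of 3 Dox arrays above all controls in LSK cells. The difference between the cell types was -0.84 (limma adjusted p = 0.0724). With the compounds it rose by 1.03 in AML cells (limma adjusted p = 0.00553) and changed by 0.27 in LSK cells (limma adjusted p = 0.338). A hypothesis was erythroid differentiation. The higher of the erythroid list medians under Dox in the 2 cell types was 0.0117, which argues against a change of the whole list. The 12 genes tested include Klf1 (0.13 in AML and -0.16 in LSK cells) and Gata1 (0.15 and -0.11), neither of them called. The adult globin genes of the list were not analysed here, since no probe set was paired with each of them alone. Induction of Hbb-y apart from that program may be a hypothesis, and was not tested.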
